A study of Mus musculus with 19 samples.

How the data were processed

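RNA was sequenced from 19 libraries of C57BL/6 mouse CD8 T cells in 7 groups. Of these, 15 libraries in 5 groups of 3 came from cells sorted directly from mice, and 4 libraries in 2 groups of 2 came from cells transduced in culture. Per the labels' protocols, RNA was amplified with a SMART-Seq v4 kit, made into libraries with a Kapa kit and sequenced as paired ends on a HiSeq instrument. Samples were grouped by the labels alone.

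The deposited tables hold whole-number counts of fragments per gene for each library, not normalized, per the file headers. The authors counted with featureCounts 1.6.2 in paired-end mode, summed by gene name against GENCODE M17 on GRCm38, per the file headers. The submitters' processing notes name FastQC, STAR, featureCounts and DESeq2 with GRCm38/mm10; versions of the other tools are not given in the sources used here. The file headers show no strand option, so reads of a gene and of an overlapping or antisense gene were counted without telling them apart. Values are therefore uncertain for the clone-named loci (RP23 and RP24 names), for Tmevpg1, and for members of gene families with near-identical copies, among those named Cd200r2, Cd244, Trim30c, Ly6i, H2-Q2, Klrc1, Klre1, Oas1a and Bambi-ps1. The amplified reads carry no molecular identifiers, so intervals and lower bounds cover counting error only. Reads from the coding sequence of a TOX vector would be counted as Tox. Each table lists 53656 genes; 5 gene names gather loci on several chromosomes or strands, and all of them stayed in the tables. Coordinates are those of the deposited tables (GRCm38), counted from 1. The supplied reference annotation is of another release and was not used here.

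Library totals ran from 37006508 to 54195918 counts. At these totals a gene without counts in a library has an upper limit of 3 counts, or 0.0554 to 0.0811 CPM (normalized counts, as edgeR defines them). Within groups, library pairs differed by far more than sampling noise (chi-square per degree of freedom from 27.1 to 438), so every library was kept as its own sample. The labels do not say that replicates are separate animals or cultures, so p-values measure the spread between these samples, part of which may be technical.

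Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, robust quasi-likelihood F tests). The 15 ex vivo libraries were fitted together with a coefficient per group and 16404 genes, and the 4 cultured libraries in a fit of their own with 14614 genes. A fit of all 19 libraries with 18608 genes gave the difference between the cultured and the day 8 to 9 effects. Adjusted p-values are Benjamini-Hochberg values from edgeR over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 fold changes are standard errors worked back from the F statistic and the fold fitted without a prior count. The printed folds include the prior count, so for genes near 0 in a group these errors are approximate. Errors of CPM are standard deviations between libraries. For a gene at 0 in every library of a group, the fold is a lower bound against a floor of 3 counts over the group; with 1 to 3 counts the ratio has its 95% counting interval. Other fitted folds of genes near 0 depend on the prior count.

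Before the data were examined, 24 gene lists were fixed: sort markers (Pdcd1, Lag3, Entpd1), other inhibitory receptors, exhaustion-linked transcription factors, naive and memory genes, cytotoxic genes, cytokines and chemokines, effector and NK-type receptor genes, costimulatory receptors, tissue residency, cell cycle, glycolysis, oxidative phosphorylation, interferon response, dissociation and stress, T cell identity, and 9 lists of other cells (hepatocyte, macrophage, dendritic, neutrophil, B, NK, CD4 T, endothelial and stromal, erythroid and platelet). Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each with Benjamini-Hochberg adjustment over the lists of a comparison; camera asks whether a list moved relative to other genes. Sets taken from one comparison (all genes called each way up to 200, or the 50 smallest p-values each way where fewer than 20 were called) were tested in another by the same means.

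The genes named were fixed by a rule. In the SV40-I against OT-I, marker-high against marker-low and TOX-GFP against GFP comparisons these were Tox, the sort markers, the 2 members with the smallest p of each T cell list, and the 5 largest rises and falls among called genes whose replicates did not overlap, with at least 10 CPM in the higher group. In the other comparisons they were Tox and those 5 rises and falls. A gene that the rule names is not reported here. Other list members, Bambi-ps1, H2-Q2, Itm2a, Aqp3, Nfkbid, Xist and Ddx3y are given as further examples chosen after their values were seen. For every called gene named from the lists or the rule, replicates of the groups compared did not overlap. The rule required this of the largest rises and falls, and the other genes were called ones. Chance gives it in 10% of genes for 3 against 3, but for genes chosen in these ways it is no further support.

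Alternatives fixed at the same time were RLE size factors, library size alone, no filter, a stricter filter (at least 5 CPM in 3 ex vivo or 2 cultured libraries), limma-voom, DESeq2 1.42.0, leaving out 772 genes (receptor and immunoglobulin segments, mitochondrial genes and lists of other cells), the replicate number as a block, the number in the names of the deposited tables as a block, other sets of libraries in the fit, the summed hepatocyte list as a covariate, and leaving out each library in turn. After seeing the data, 4 were added: leaving out 3 day 20 to 21 libraries with hepatocyte RNA, leaving out 2 day 8 to 9 libraries that stood apart, the summed macrophage list as a covariate, and fitting the cultured libraries without robust estimation. Where leaving out a library left 1 in its arm, that lone library was assumed to vary like the others. The table-name numbers overlap only in part between compared groups. SV40-I 3, OT-I 1, marker-high 3 and marker-low 1 each have a number to themselves, so that block takes them out of the effect.

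The edgeR and camera steps were tested on simulated data with seed 1, with 100 genes changed by 2-fold and 100 by 4-fold; the real tables had been analysed before this test was written. With shrunken dispersions, the 4-fold changes were called for 33% of genes in a simulated SV40-I against OT-I comparison (15478 genes tested), 31% for marker-high against marker-low (15469 genes) and 97% for the cultured cells (14120 genes); for 2-fold changes the shares were 5%, 2% and 63%. That version had less spread between genes than the real cultured data (prior degrees of freedom 21.6 against 3.83). A second version came closer, at 3.96 in culture, and at 3.66 and 3.5 for the ex vivo comparisons against 2.93 in the real data. It called 16% (15284 genes), 18% (15239 genes) and 39% (14018 genes) of 4-fold changes, and 0%, 0% and 2% of 2-fold changes. The ex vivo shares may still be too high. Genes were simulated independently of each other, so camera was not tested on correlated genes. Regroupings of libraries were drawn with seed 2.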

Results

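Gene expression was measured by RNA sequencing in CD8 T cells that carry a known receptor. SV40-I cells recognise a peptide of the SV40 large T antigen, and OT-I cells recognise a peptide of ovalbumin. Ex vivo groups of 3 libraries each were naive SV40-I cells and SV40-I and OT-I cells from malignant liver lesions at days 20 to 21. A further pair of ex vivo groups held SV40-I cells from such lesions at days 8 to 9, labelled as high or low for the surface proteins PD1, LAG3 and CD39 (marker-high and marker-low). Column headings of their tables carry the letters WT for marker-high and KO for marker-low libraries, while the labels give no genotype. Whether these groups differ by sorting gate, by genotype or by both is therefore not certain. The lesion origin follows the titles and context labels, whereas the source field names splenocytes for every library, so the tissue sampled is not certain. Cultured groups of 2 libraries each were naive SV40-I cells stimulated with antibodies to CD3 and CD28 and transduced with a retrovirus carrying TOX and GFP or GFP alone. Depth was similar across the 19 libraries, with totals from 37006508 to 54195918 counts.

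Receptor segments were used to check the labels. Trbv12-1 stood at 163 to 168 CPM in the OT-I libraries and at no more than 1.36 CPM in any other library. Trbv29 stood at 3220 ± 653 CPM in SV40-I cells at days 20 to 21 and 2.22 ± 0.0265 CPM in OT-I cells (n = 3 each). Trav14 segments, planned as a further OT-I mark, did not mark these cells. Trav14n-3, the only such segment to reach 30 CPM in any library, stood at 0.189 to 0.679 CPM in OT-I libraries. It stood at 10.3 to 39.1 CPM in marker-low libraries and at no more than 2.37 CPM elsewhere. Trav7-1 stood at 39.6 CPM in SV40-I library 3 of days 20 to 21 and at no more than 0.663 CPM elsewhere. Tox (chromosome 4, 6686353 to 6991557, minus strand), which encodes a transcription factor linked to T cell exhaustion, stood at 102 ± 19.3 CPM in naive cells. At days 20 to 21 it stood at 855 ± 144 CPM in SV40-I and 24.6 ± 6.15 in OT-I cells, and at days 8 to 9 at 553 ± 187 in marker-high and 93.7 ± 42.6 in marker-low cells (n = 3 each). In culture it stood at 137 ± 27.4 CPM with TOX-GFP and 17.6 ± 5.30 CPM with GFP (n = 2 each), and the former value may include reads of the vector's coding sequence.

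**Figure D1:**
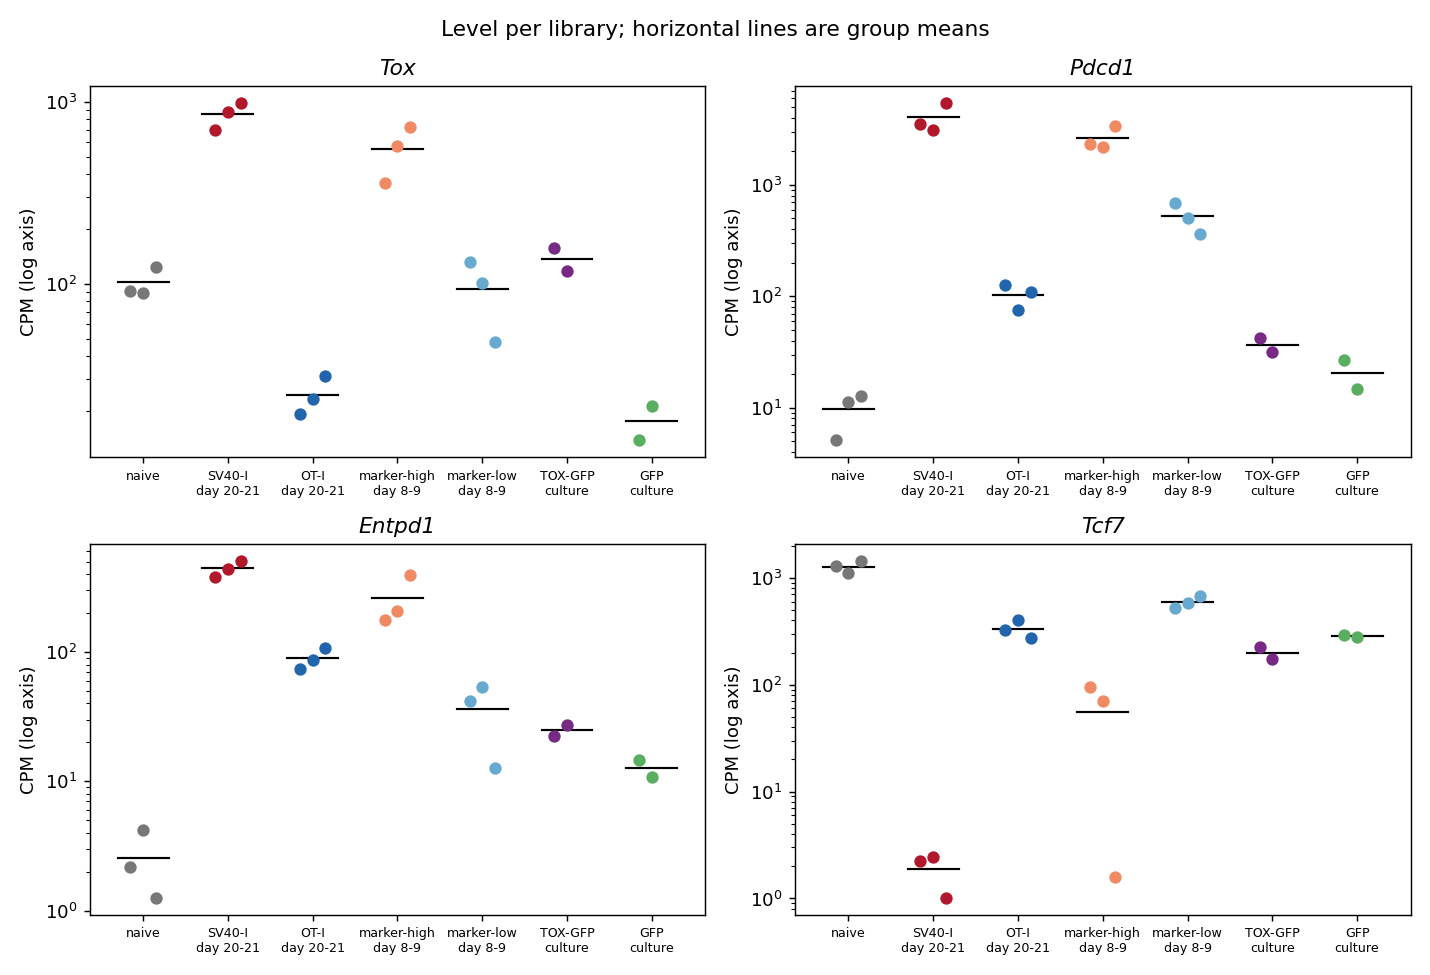
Levels of Tox, Pdcd1, Entpd1 and Tcf7 in CPM on log axes, with a point per library, colours for the 7 groups and horizontal lines at group means. Ex vivo and cultured libraries were normalized separately. Mean Tox was 855 CPM in SV40-I cells at days 20 to 21 against 24.6 in OT-I cells, while mean Tcf7 was 1.90 against 334; marker-high library 3 lies at 1.57 CPM of Tcf7, below the 71.0 and 94.3 of the other marker-high libraries.

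The comparison of SV40-I with OT-I cells at days 20 to 21 asked how T cells specific for the tumour antigen differ from cells of another specificity in such lesions. Tox and the genes of the 3 sort markers were higher in SV40-I cells. Tox was higher by 5.12 ± 0.41 on the log2 scale (adjusted p = 1.26e-05). Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes PD1, was higher by 5.29 ± 0.42 (4043 ± 1251 against 103 ± 26.3 CPM) and Lag3 by 5.36 ± 0.51 (75.4 ± 38.9 against 1.83 ± 0.450 CPM). Entpd1, which encodes the ectoenzyme CD39, was higher by 2.31 ± 0.52 (adjusted p = 0.0138). The costimulatory receptor Tnfrsf9, known as 4-1BB, rose by 6.08 ± 0.40 to 1564 ± 296 CPM, and the chemokine Ccl4 by 3.59 ± 0.31 to 1250 ± 286 CPM. Genes of naive and memory cells fell, with the IL-7 receptor gene Il7r at -10.32 ± 1.32, the transcription factor genes Lef1 at -7.72 ± 0.99 and Tcf7 at -7.45 ± 1.08. The terminal effector marker Klrg1 fell from 290 ± 65.6 CPM in OT-I to 1.07 ± 0.419 CPM in SV40-I cells (n = 3 each throughout). In all, edgeR called 805 genes higher and 674 lower of 16404 tested. The groups also carry different receptors, so specificity and transgenic line cannot be told apart here. Receptor segments, which differ with the receptor, were kept in these counts. Mitochondrially encoded genes took 0.051, 0.175 and 0.104% of counts in SV40-I libraries 1, 2 and 3, below the 0.233, 0.319 and 0.279% in OT-I libraries.

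By list, 3 of 3 sort markers rose (3 adjusted over the list alone; camera adjusted p = 3.17e-12, and 0.00106 with an estimated correlation). Of 10 other inhibitory receptors 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.000642). Tigit rose by 4.03 ± 0.43 and Cd244 by 5.22 ± 1.23, while Btla, an inhibitory receptor abundant on resting lymphocytes, changed by -4.62 ± 0.70. Of 15 exhaustion-linked transcription factors 5 rose (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.00583), among them Nr4a2 by 7.99 ± 1.07, a factor induced by receptor signalling, and Tox2, at least 251-fold higher. Of 15 naive and memory genes 10 fell (13 adjusted over the list alone; camera adjusted p = 7.56e-16). Of 13 effector and NK-type receptor genes 7 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 2.13e-06). Those that fell included S1pr5, a receptor for leaving tissue, at -9.38 ± 1.66 and Cx3cr1 at -4.70 ± 1.08. These calls held with an estimated correlation (adjusted p of 0.0205, 0.0379, 0.0215 and 0.00338 for the last 4 lists). Of 13 cytokines and chemokines 4 rose, among them Ccl3 by 5.27 ± 0.48, and Il2 changed by -5.18 ± 1.15 (5 up and 1 down adjusted over the list alone; camera adjusted p = 0.00243). Of 15 interferon response genes 6 fell (7 adjusted over the list alone; camera adjusted p = 2.35e-06), with Usp18 at -2.62 ± 0.35 and Ifit3 at -4.03 ± 0.58. For both lists the call was lost, with an adjusted p = 0.225 with an estimated correlation, and the transcription factor and cytokine lists lost theirs with a stricter filter (0.0742 and 0.0536, the highest of their alternatives but for the estimated correlation).

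Other T cell lists moved both ways. Of 11 cytotoxic genes Gzma rose by 2.40 ± 0.66 while Gzmm (-7.38 ± 1.32) and Serpinb9 (-1.33 ± 0.30) fell (2 up and 2 down adjusted over the list alone; median 0.54, mean -0.26; camera adjusted p = 0.645). Of 9 costimulatory receptors Tnfrsf9 and Tnfrsf4 rose while Cd28 (-3.95 ± 0.82) and Cd2 (-1.87 ± 0.37) fell (3 and 2 adjusted over the list alone; median -0.46, mean 0.32; camera adjusted p = 0.545). Of 15 glycolysis genes Tpi1 rose by 0.96 ± 0.27 and Pfkp (-0.53 ± 0.14) and Slc2a1 (-0.92 ± 0.26) fell (3 and 3 adjusted over the list alone; median -0.13, mean 0.03; camera adjusted p = 0.986). The 17 oxidative phosphorylation genes had a median of 0.11 (camera adjusted p = 0.545). Of 9 tissue residency genes Cd69 fell, at -2.29 ± 0.50 (1 adjusted over the list alone; camera adjusted p = 0.986). Of 14 dissociation and stress genes the chaperone genes Hspa8 (-1.78 ± 0.30) and Dnajb1 fell (2 adjusted over the list alone; camera adjusted p = 0.545). Of 10 T cell identity genes Trac rose by 2.57 ± 0.27, Cd3e by 1.44 ± 0.18 and Cd8a by 1.28 ± 0.17 (3 up and 2 down adjusted over the list alone). Trac, the largest of these, encodes part of the receptor itself, which differs between the groups. Camera's adjusted p for that list was 0.0390, with an adjusted p = 0.724 with an estimated correlation, 0.0754 without OT-I 1 and 0.241 without OT-I 2. That call also ended without a filter (0.101), with the stricter filter (0.112), without segments, mitochondrial and other-cell genes (0.401) and with the table-name number as a block (0.228). With fry the calls of T cell identity (0.107) and of erythroid and platelet genes (0.0566) ended. The 24 cell cycle genes had a median of -0.03 and a mean of 0.02 (camera adjusted p = 0.986), with Pcna at -0.75 ± 0.31 (adjusted p = 0.163).

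The largest rises were in Sfrp4, a secreted Wnt antagonist (at least 2040-fold higher), Insrr, an insulin receptor-related kinase (at least 1510-fold), the endocytic receptor gene Mrc2 (ratio 13100, interval 3630 to 108000), Cd200r2 (12.83 ± 2.51) and RP23-128L6.4 (at least 710-fold). The largest falls were in the potassium channel gene Kcnj8 (ratio 32000, interval 5750 to 1260000), the death-domain receptor gene Tnfrsf25 (ratio 7700, interval 2130 to 63600), Trim30c (at least 662-fold lower), RP23-14O16.2 (at least 540-fold lower) and Tmevpg1 (at least 513-fold lower). Hepatocyte transcripts differed between libraries, at 41.3, 1134 and 2063 summed CPM in OT-I libraries 1, 2 and 3 and 48.8, 1605 and 76.2 in SV40-I libraries 1, 2 and 3. Erythroid and platelet transcripts were at 1765, 3642 and 1327 CPM in OT-I against 99.0, 584 and 806 in SV40-I libraries, beside the interferon and naive genes that were also higher in OT-I cells. That list had a median of -2.13 (camera adjusted p = 0.00583, and an adjusted p = 0.466 with an estimated correlation; 0.0654 without SV40-I library 1). Among other lists of other cells, 1 of 6 dendritic genes fell (Itgax, an integrin also found on activated T cells, -7.42 ± 1.01) and 1 of 8 B cell genes rose (Ighm, 1.21 ± 0.17). Of the NK list 1 of 6 genes rose (Fcer1g, 4.06 ± 0.65; list median -1.31, mean -0.95, though camera pointed up). In the CD4 T list 1 of 4 genes fell (Cd40lg, at least 417-fold lower) and in the endothelial and stromal list 1 of 10 (Pecam1, -1.59 ± 0.33). Adjusted over the list alone, these counts were the same except 2 for NK genes. Camera's adjusted p was 0.386 for hepatocyte (median -0.89; 0.00419 without OT-I 1, 0.000494 without SV40-I 2 and 0.00235 with the table-name block) and 0.986 for macrophage genes (median 0.48, mean -0.10). It was 0.392 for dendritic (median -0.67, or -0.36 with genes at 0 in a group at their bounds), 0.433 for neutrophil (median -0.66; 0.0410 without SV40-I 2 and 0.0352 without the 3 libraries richest in hepatocyte transcripts), 0.392 for endothelial and stromal and 0.545 for B, NK and CD4 T lists.

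Without the 3 libraries richest in hepatocyte transcripts (SV40-I 2, OT-I 2 and OT-I 3; chosen after seeing the data), edgeR called 83 genes higher and 144 lower, 212 of them among the 1479. This left 2 SV40-I libraries and 1 OT-I library. Entpd1 then stood at 2.55, beside 2.31 with all libraries, with an adjusted p = 0.307, the highest of its alternatives, which began at 0.000229. Calls of other named genes ended too, among them those of Ifit3 (-3.71, adjusted p = 0.0538), S1pr5 (-9.88, 0.0923), Btla (-3.87, 0.102), Tox2 (0.104) and the 5 largest rises (up to 0.360), each in an unchanged direction. With the summed hepatocyte list as a covariate and all libraries kept, edgeR called 652 genes higher and 571 lower, 1178 of them among the 1479. No named gene lost its call there, while the T cell identity list did (0.0970, and 0.231 without the 3 libraries). DESeq2 called 1387 higher and 1127 lower, and the number in the table names as a block gave 392 and 415. With that block SV40-I 3 and OT-I 1 no longer bear on the effect, since neither shares its number with the other group. Leaving out OT-I 1, 2 or 3 gave 471, 423 and 462 genes higher (449 lower without OT-I 2) and leaving out SV40-I 1 gave 527 higher. Of the called named genes 27 kept their call without any 1 library. Calls were lost without OT-I 1 (Entpd1 at 0.0651, Pfkp, Sfrp4 and Slc2a1, up to 0.152), OT-I 2 (Entpd1 at 0.0637 and Sfrp4 at 0.0641) or OT-I 3 (Pfkp, Serpinb9, Sfrp4 and Slc2a1, up to 0.108). Calls also ended without SV40-I 1 (Serpinb9 at 0.0616), SV40-I 2 (Pfkp, Serpinb9 and Slc2a1, up to 0.159) or SV40-I 3 (Cd69, Pfkp and Slc2a1, up to 0.123).

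The day 8 to 9 comparison asked how SV40-I cells with high surface PD1, LAG3 and CD39 differ early from cells low for them. Tox was higher in marker-high cells by 2.56 ± 0.36 on the log2 scale (adjusted p = 0.00662). Genes of the labelled markers were higher too, Pdcd1 by 2.34 ± 0.37 (2648 ± 654 CPM in marker-high cells) and Entpd1 by 2.84 ± 0.53 (259 ± 120 against 36.2 ± 21.2 CPM), while Lag3 differed by 1.37 ± 0.43 (adjusted p = 0.185). Of the granzyme genes, Gzmb was higher by 3.23 ± 0.42 (3158 ± 759 CPM in marker-high cells) and Gzma by 4.70 ± 0.73 (2091 ± 718 against 80.6 ± 77.9 CPM), while Gzmm was lower (-6.24, adjusted p = 0.0313). The chemokine receptor gene Cxcr6, known from tissue-resident cells, rose by 4.24 ± 0.53 (1105 ± 996 against 58.4 ± 12.9 CPM). Calcb (chromosome 7, 114718643 to 114723365, plus strand), which encodes a calcitonin gene-related peptide, rose by 6.66 ± 0.47 (97.1 ± 24.0 against 0.963 ± 0.246 CPM). The cytokine genes Tnf (-2.74 ± 0.48) and Il2 (-5.44 ± 1.11) and the receptor-induced factor Nr4a1 (-2.43 ± 0.46) were lower in marker-high cells (n = 3 each throughout). Of 16404 genes edgeR called 78 higher and 118 lower, with the spread of each gene estimated over all 15 ex vivo libraries. Mitochondrially encoded genes took 0.116, 0.164 and 0.118% of counts in marker-high and 0.214, 0.15 and 0.221% in marker-low libraries. Column headings of the deposited tables carry the letters WT for marker-high and KO for marker-low libraries while the labels give no genotype, so a difference of genotype stays open.

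By list, 2 of 3 sort markers rose (3 adjusted over the list alone; camera adjusted p = 1.20e-08, and 0.00291 with an estimated correlation). The groups are labelled by the products of these genes, so this is not independent evidence if the label was a sorting gate. Of 15 naive and memory genes 1 fell (Satb1, a chromatin organiser, -4.61 ± 0.83; 11 adjusted over the list alone; camera adjusted p = 5.29e-18, and 0.0131 with an estimated correlation), with Id3 at -2.27 ± 0.51 (adjusted p = 0.0526). Of 24 cell cycle genes 2 rose (Aurka, 1.63 ± 0.30, and Plk1, 1.39 ± 0.30, both mitotic kinases; 9 adjusted over the list alone; camera adjusted p = 4.68e-11, and an adjusted p = 0.0889 with an estimated correlation). Of 13 cytokines and chemokines 2 fell (3 up and 6 down adjusted over the list alone; camera adjusted p = 0.00101, and an adjusted p = 0.143 with an estimated correlation). Of 11 cytotoxic genes 2 rose and Gzmm fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.00445, and an adjusted p = 0.274 with an estimated correlation). Of 9 tissue residency genes Cxcr6 and Zfp683 (3.10 ± 0.60), a residency transcription factor, rose while Cd69 fell (-2.54 ± 0.51). Of that list 3 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0421, and an adjusted p = 0.399 with an estimated correlation). Of 15 exhaustion-linked transcription factors Nr4a1 fell (2 up and 6 down adjusted over the list alone; camera downward at an adjusted p = 0.0384, and an adjusted p = 0.143 with an estimated correlation; median 0.15, mean -0.49). Of 10 other inhibitory receptors Tigit rose, by 2.19 ± 0.39 (5 adjusted over the list alone; camera adjusted p = 0.334). Of 10 T cell identity genes Cd8a rose, by 1.01 ± 0.17 (1 adjusted over the list alone; camera adjusted p = 0.979; median -0.13, mean -0.09, though camera pointed up). The residency call ended without marker-low 1 or 3 (adjusted p of 0.341 and 0.143), without a filter (0.0597) and with the stricter filter (0.0603). It also ended in a fit of both groups alone (0.110), with the table-name number as a block (0.364), and with the hepatocyte or macrophage list as a covariate (0.0581 and 0.116). The cytotoxic call ended without marker-low 2 (0.237), in the fit of both groups alone (0.117) and without marker-low 2 and marker-high 3 together (0.0544). The transcription factor call ended without marker-low 2 or marker-high 3 (0.152 and 0.0906) or both (0.237), without a filter (0.0597) and with the table-name block (0.0812). That block also ended the cytokine call (0.238).

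Median log2 changes of the remaining T cell lists were 0.30 for effector and NK-type receptor genes (camera adjusted p = 0.670), -0.44 for costimulatory receptors (0.599), -0.01 for glycolysis (0.706), and 0.02 for oxidative phosphorylation (0.916; camera pointed down). That of interferon response genes was 0.34 (0.907), and without marker-high 3 it was -0.45 with an adjusted p = 0.00521. That of dissociation and stress genes was -0.45 (camera adjusted p = 0.0384, and an adjusted p = 0.399 with an estimated correlation; 0.306 without marker-low 2, 0.332 without marker-high 3, 0.829 without both and 0.158 with the table-name block). Macrophage transcripts were at 6058, 4091 and 4776 summed CPM in marker-high libraries 1, 2 and 3 and 2030, 8854 and 742 in marker-low libraries, beside the cytotoxic and residency genes that were higher in marker-high cells. The list had a median of 0.98 (camera adjusted p = 0.00797, and an adjusted p = 0.676 with an estimated correlation; 0.517 without marker-low 3 and 0.0847 without marker-high 1). In marker-low library 2 neutrophil transcripts stood at 3047 CPM, and T cell identity genes, at 11360 CPM, were lowest there. Across genes, which are not independent replicates, its log2 CPM correlated at a mean r of 0.902 with marker-high libraries and 0.892 with the other marker-low libraries. The other ex vivo libraries correlated best with their own group. With fry the cytotoxic (0.0576), residency, stress (0.171 each) and macrophage calls (0.399) ended, and other inhibitory receptors passed (0.0282). Cell cycle transcripts were at 9239, 10140 and 5411 CPM in marker-high libraries 1, 2 and 3 and 4426 to 4628 CPM in marker-low libraries. Among other cells, 1 dendritic gene rose (Xcr1, 3.47 ± 0.73; list median -1.38 and mean -0.73, though camera pointed up at an adjusted p = 0.769). Cd22 of the B list (-2.09 ± 0.41; 0.338) and Pecam1 of the endothelial list (-1.75 ± 0.33; median 0.34, mean 0.93, camera pointing down at 0.916) fell. Each of these calls also stood adjusted over the list alone. Medians were -1.16 for hepatocyte (camera adjusted p = 0.144; 0.0130 without marker-low 3, and 0.00239 and 0.000504 with the hepatocyte and macrophage covariates), -1.38 for neutrophil (0.457; 3.53e-05 with the macrophage covariate), 0.80 for NK (0.391), and -0.15 for CD4 T genes (0.979). Erythroid and platelet genes had a median of 0.53 (mean -0.35, camera pointing down; 0.391, and 0.00521 without marker-high 3, 0.00785 with the table-name block and 0.00458 with the macrophage covariate, with which B cell genes passed too).

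The largest rises also took in the hormone receptor genes Glp1r (at least 1170-fold higher) and Vipr2 (at least 987-fold), Kndc1 (ratio 2850, interval 512 to 113000) and Ccdc80 (9.56 ± 2.00), a matrix gene. The largest falls took in RP23-284K1.6 (-10.25 ± 1.00; chromosome 7, 140247284 to 140300736), its neighbour Cd163l1 (-6.77 ± 1.41; chromosome 7, 140218267 to 140231145), and the transporter gene Slc16a5 (-8.38 ± 1.42). In a fit of the 6 compared libraries alone 1 gene was higher and 3 lower. Tox then had an adjusted p = 0.108, the highest of alternatives that began at 1.60e-08. DESeq2 called 341 and 412, limma-voom 150 and 193, and the number in the table names as a block left 2 and 3. With that block marker-high 3 and marker-low 1 no longer bear on the effect, since neither shares its number with the other group. Without marker-high library 3 and marker-low library 2 (chosen after seeing the data) 45 and 62 were called, 73 of them among the 196. Leaving out marker-low 1 or 3 gave 37 and 13 higher and 55 and 25 lower. Leaving out marker-high 1, 2 or 3 gave 71, 34 and 71 lower (47 higher without marker-high 2). Of 23 called named genes 7 (Tox, Gzma, Gzmb, Cxcr6, Calcb, Kndc1 and RP23-284K1.6) kept their call without any 1 library. Of the others, 10 calls were lost without marker-low 1 (adjusted p of 0.0623 to 0.137), 8 without marker-low 2 (0.0548 to 0.0892) and 15 without marker-low 3 (0.0510 to 0.204, Pdcd1 at 0.0625 among them). Leaving out marker-high libraries, 6 were lost without marker-high 1 (0.0507 to 0.131), 8 without marker-high 2 (0.0671 to 0.166) and 9 without marker-high 3 (0.0546 to 0.124).

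The culture comparison asked what forced TOX expression changes in T cells without a tumour. Tox transcripts were higher with TOX-GFP by 2.96 ± 0.26 on the log2 scale. Of 14614 genes edgeR called 0 (smallest adjusted p = 0.207), 1906 had an unadjusted p under 0.05 (1216 higher, 690 lower), limma-voom called 0 and DESeq2 called 393 higher and 101 lower. Adjusted over the list alone, 15 of 24 cell cycle genes were higher (camera adjusted p = 8.20e-22), with Ccna2, cyclin A2, at 1.03 ± 0.10 (337 ± 7.57 against 165 ± 3.79 CPM, n = 2 each) and Ccnb1, cyclin B1, at 0.93 ± 0.11. Adjusted over the list alone, 7 of 10 effector and NK-type receptor genes were higher (camera adjusted p = 2.81e-09), with the NK receptor genes Klrb1c at 2.95 ± 0.45 and Klrk1 at 1.19 ± 0.20. So were 5 of 11 cytotoxic genes (5.04e-06), with perforin, Prf1, at 1.82 ± 0.45. By the same adjustment 7 of 15 naive and memory genes were lower (camera adjusted p = 3.90e-05), with Id3 at -0.59 ± 0.11 and Ccr7 at -0.55 ± 0.12. Also lower were 6 of 10 T cell identity genes (4.79e-06), with Thy1 at -1.07 ± 0.30. With an estimated correlation these calls were lost, at an adjusted p = 0.187 for cell cycle, 0.620 for naive and memory and 0.434 for the other 3 lists. With fry they were lost too (0.126 to 0.233), and the naive and memory call also with all 19 libraries in 1 fit (0.0994).

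Adjusted over the list alone, Entpd1 among 3 sort markers was higher with TOX-GFP (0.96 ± 0.22; camera adjusted p = 0.0665), with Pdcd1 at 0.83 ± 0.32 and Lag3 at -0.02 ± 0.45. By this adjustment 2 of 10 other inhibitory receptors were higher (Havcr2, 1.23 ± 0.22, and Cd244, 1.37 ± 0.26; camera adjusted p = 0.153), as was 1 of 15 exhaustion-linked transcription factors (Eomes, 1.21 ± 0.18; list median -0.09 and mean -0.12, though camera pointed up at 0.877). Of 9 costimulatory receptors 1 was higher and 3 lower (Cd2, -0.46 ± 0.10, and Cd27, -0.63 ± 0.16, among the latter; 0.0727). Medians were 0.09 for cytokines and chemokines (0.759), 0.07 for tissue residency (0.877), 0.08 for glycolysis (0.181), and -0.09 for oxidative phosphorylation genes (0.120). They were 0.06 for interferon response (0.812) and 0.04 for dissociation and stress genes (0.877). For residency and interferon genes camera pointed down. Sort markers passed without a filter (0.0423), with the stricter filter (0.0186), without segments, mitochondrial and other-cell genes (0.0429), with the replicate number as a block (0.0201), and with all 19 libraries in 1 fit (0.0159). They also passed without TOX-GFP 2 or GFP 1 (0.0384 and 0.000264). Costimulatory receptors (0.0423), oxidative phosphorylation and CD4 T genes (0.0483 each) passed without a filter, other inhibitory receptors without TOX-GFP 2 (0.0326) and glycolysis without TOX-GFP 1 or GFP 1 (0.00111 and 0.00242). Few genes of other cells were measured in culture, and camera's adjusted p was 0.0727 for CD4 T genes and at least 0.296 for the other such lists; without TOX-GFP 2 it was 0.00422 for CD4 T and 0.0173 for macrophage genes. Leaving out GFP 1 or GFP 2 gave 177 and 1021 genes higher and 40 and 379 lower, leaving out TOX-GFP 2 gave 1, and the fit without a filter gave 6. Tox itself had an adjusted p = 0.0179 without a filter, 6.63e-34 with DESeq2, and 0.0266, 0.0133 and 0.0202 without TOX-GFP 2, GFP 1 and GFP 2, in a range reaching 0.212.

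The ex vivo comparisons of SV40-I with OT-I and of marker-high with marker-low cells share no libraries. Of their calls, 57 genes were higher in both and 84 lower in both, where independent lists would share 3.83 and 4.85, and 3 went opposite ways (Itm2a, 1.70 against -1.66; H2-Q2, 2.77 against -2.81; Bambi-ps1, 3.09 against -2.41). Both comparisons came from the same fit with a shared spread per gene, so genes of low estimated spread are more readily called in both. The values of 3.83 and 4.85 may therefore be too low as a reference. The genes higher in marker-high cells rose as a set in SV40-I against OT-I cells (camera adjusted p = 9.85e-69, and 0.000180 with an estimated correlation) and the lower set fell (6.88e-75, and 1.65e-05). Across all genes, which are not independent replicates, fold changes correlated with r = 0.323 (rho = 0.268), and with r = 0.176 without a filter and 0.594 among genes above 3 in mean log2 CPM. The difference between both effects was called for 169 genes. Of the genes higher with TOX-GFP, the 50 with the smallest p-values, Tox among them, were higher as a set in marker-high than marker-low cells (median 0.92; camera adjusted p = 1.89e-05, and 0.0412 with an estimated correlation). The 50 with the smallest p-values among lower genes were lower as a set (median -0.72; 1.97e-09, and an adjusted p = 0.0911 with an estimated correlation). In SV40-I against OT-I cells the medians were -0.24 and -0.24 (0.403 and 0.101), and the correlations with the TOX-GFP effect were 0.012 (rho = -0.02) and, for marker-high against marker-low, 0.127 (rho = 0.206).

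**Figure D2:**
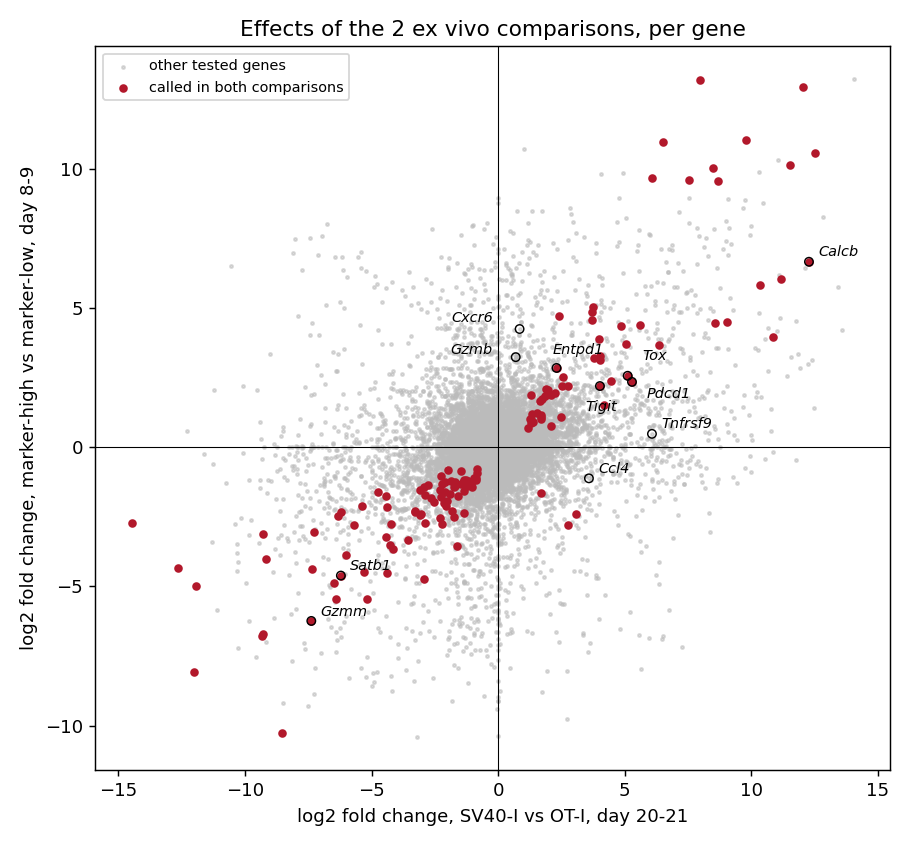
Each point is 1 of 16404 genes, with the log2 fold change of SV40-I against OT-I cells on the horizontal axis and that of marker-high against marker-low cells on the vertical axis. Red points are genes called in both comparisons, 57 higher and 84 lower in both and 3 opposite, and ringed points are named, among them Tox at 5.12 and 2.56 and Tnfrsf9 at 6.08 and 0.48.

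Against naive SV40-I cells, SV40-I cells at days 20 to 21 had 1829 genes higher and 1125 lower. Mitochondrially encoded genes took 0.199 to 0.307% of counts in naive libraries, above the 0.051 to 0.175% in these cells. Tox rose by 3.07 ± 0.37 (adjusted p = 0.000107). The largest rises were in Calcb (at least 10200-fold higher), Mrc2 (at least 9810-fold), Csdc2, an RNA-binding protein gene (at least 6300-fold), RP24-95J4.3 (at least 5840-fold) and the protease gene Tmprss6 (ratio 29100, interval 5230 to 1150000). The largest falls were in Gabrr2 (at least 1350-fold lower), the amino acid transporter gene Slc6a19 (-13.03 ± 1.56), RP23-400O10.4 (at least 892-fold lower), Cyp2s1 (ratio 9220, interval 1650 to 364000) and Adgrb2 (at least 805-fold lower). OT-I cells, whose receptor differs from that of the naive cells, had 830 genes higher and 376 lower, and Tox fell, at -2.05 ± 0.36 (adjusted p = 0.00302). Their largest rises were in the effector genes Cx3cr1 (ratio 41400, interval 7430 to 1640000) and Klrg1 (13.23 ± 1.49), in Plcd1 (at least 1580-fold higher) and in Car5b (ratio 9320, interval 1670 to 368000). Ambp, whose product is secreted by liver, was at least 1350-fold higher (adjusted p = 0.0104, from 1.96e-11 to 0.131 over alternatives) in libraries that held hepatocyte transcripts. Their largest falls were in Ampd1 (at least 1360-fold lower), RP23-383A19.1 (at least 522-fold lower), the prohormone convertase gene Pcsk1 (ratio 4650, interval 1590 to 22600), RP23-469H5.3 (ratio 4540) and RP23-42O8.9 (ratio 3320, interval 596 to 131000). DESeq2 called 1650 and 802 for OT-I cells and 1756 lower for SV40-I cells. Leaving out naive 1, 2 or 3 or OT-I 1, 2 or 3 gave 229, 224, 234, 189, 217 and 218 genes lower in OT-I cells, with 549 higher without naive 2 and likewise without naive 3.

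Marker-high cells had 2349 genes higher and 1492 lower than naive cells, and Tox rose by 2.44 ± 0.36 (adjusted p = 0.000446). Their mitochondrial share, 0.116 to 0.164%, was below the 0.199 to 0.307% of naive libraries. The largest rises were in Calcb (at least 4750-fold higher), RP24-95J4.3 (at least 2720-fold), Mrc2 (at least 2640-fold), Slc9b2 (at least 2070-fold) and the mitochondrial fission gene Mtfr2 (at least 1900-fold). The largest falls were in Slc16a5 (-13.76 ± 1.58), Lman1l (at least 510-fold lower), Mmp15 (at least 467-fold lower), RP23-383A19.1 (ratio 1410, interval 253 to 55700) and Il7r (-9.94 ± 1.29). Marker-low cells had 1736 genes higher and 1018 lower; Tox differed by -0.12 ± 0.34 (adjusted p = 0.854), with 0.20 without marker-low 3 and 0.05 without naive 3. Their largest rises were in Spry1, a feedback inhibitor of receptor signalling (at least 4670-fold higher), Slc9b2 (at least 1720-fold), the interferon gamma gene Ifng (12.75 ± 0.91), Ldlrad3 (at least 884-fold) and Mtfr2 (at least 856-fold). Their largest falls were in Lman1l (at least 583-fold lower), RP23-383A19.1 (at least 545-fold lower), Calcrl (-7.51 ± 1.81), the integrin gene Itgae, which encodes CD103 (-6.05 ± 1.21), and the interferon-induced Ifit1 (-5.81 ± 1.83). Summed macrophage transcripts were at 4091 to 6058 CPM in marker-high, 742.5 to 8854 CPM in marker-low and 115.6 to 289.7 CPM in naive libraries. DESeq2 called 2311 lower for marker-high and 2641 and 1847 for marker-low cells. Leaving out naive 3, marker-high 1 or marker-high 2 gave 905, 794 and 745 genes lower in marker-high cells (1542 higher without naive 3). Leaving out naive 1, naive 3, marker-low 1 or marker-low 3 gave 598, 414, 464 and 652 lower in marker-low cells (1100 and 988 higher without naive 1 and naive 3). The calls of Ldlrad3 (0.0857 without marker-low 2 and 0.0941, 0.0894 and 0.103 without naive 1, 2 and 3), Ifit1 (0.0989 and 0.112 without marker-low 2 and 3, and 0.0628, 0.0780 and 0.120 without naive 1, 2 and 3) and Lman1l (0.0527 without naive 2) ended.

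The later SV40-I cells were also set against marker-high cells of days 8 to 9, which differ both in time and in being labelled high for PD1, LAG3 and CD39. Lists were not tested here. The centromere protein gene Cenpi was at -6.22 ± 1.38 and Mybl2, a cell cycle transcription factor gene, at -5.33 ± 1.26. The innate receptor gene Tlr1 was at -8.44 ± 0.87 (adjusted p = 0.000254), Rap1gap2 at -7.65 ± 1.01 and Ly6i at -5.51 ± 1.15. The imprinted transcript Peg13 rose by 3.73 ± 0.57 (adjusted p = 0.00249), the NK receptor gene Klrb1c by 2.96 ± 0.43, Csdc2 by 3.94 ± 0.96, Zkscan1 by 2.54 ± 0.58 and the chromatin gene Phf1 by 2.47 ± 0.41. Tox differed by 0.63 ± 0.34 (adjusted p = 0.305). Summed macrophage transcripts were at 58.5, 1098 and 876 CPM in the later libraries and 4091 to 6058 CPM in the marker-high libraries. In all 289 genes were higher and 585 lower. The 6 compared libraries alone gave 61 and 264, DESeq2 992 and 1275, no filter 171 higher, the stricter filter 457 higher and limma-voom 501 higher. Leaving out SV40-I 1, 2 or 3 gave 167, 142 and 97 higher and 388, 339 and 271 lower. Leaving out marker-high 1, 2 or 3 gave 59, 50 and 772 higher and 271, 261 and 897 lower. Named calls ended without SV40-I 1 (Cenpi and Csdc2, up to 0.0683), SV40-I 2 (Csdc2 and Zkscan1, up to 0.0982), SV40-I 3 (Cenpi, Csdc2, Zkscan1, Ly6i and Mybl2, up to 0.110), and without marker-high 1 and marker-high 2 (Cenpi, Csdc2, Mybl2 and Zkscan1, up to 0.169 and 0.115).

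**Figure D3:**
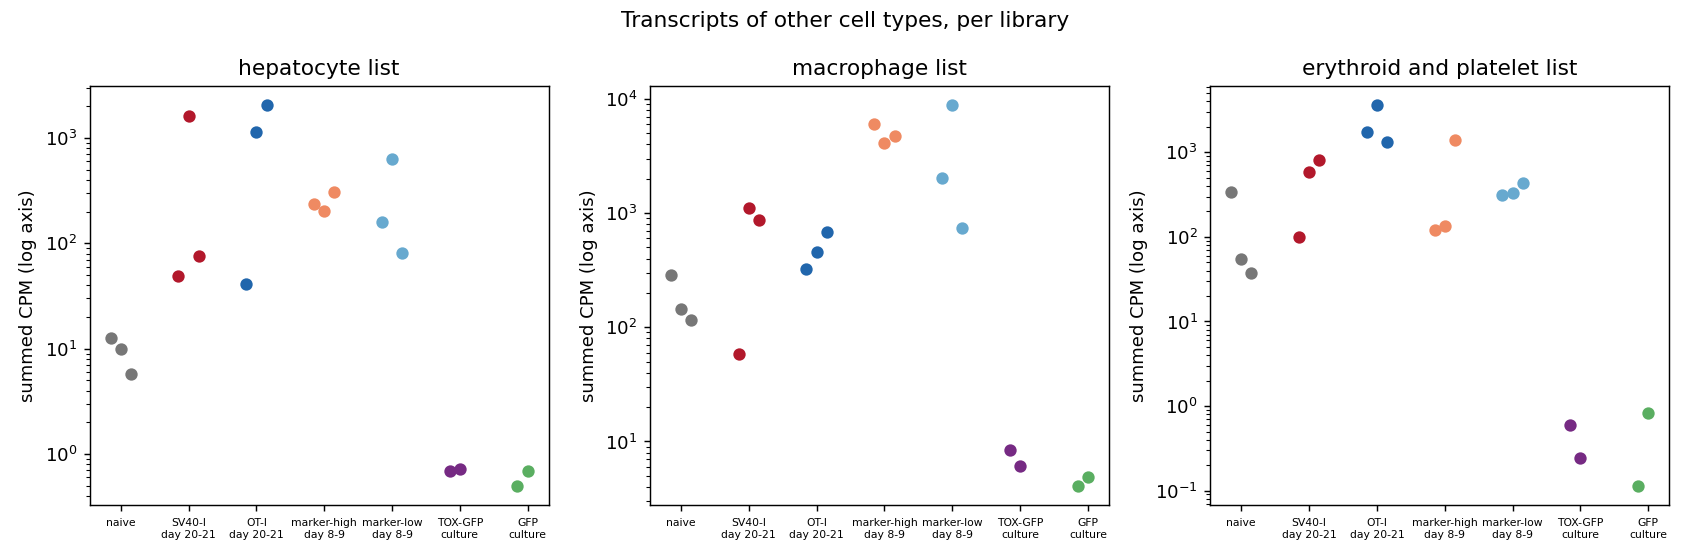
Summed CPM of the hepatocyte, macrophage and erythroid and platelet lists on log axes, with a point per library and colours for the 7 groups. Hepatocyte transcripts reach 1134 and 2063 CPM in OT-I libraries 2 and 3 and 1605 CPM in SV40-I library 2, against 5.8 to 12.7 CPM in naive cells.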

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

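The test of macrophage RNA was chosen only after the result was seen.

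The SV40-I against OT-I and marker-high against marker-low effects differed, by an edgeR test of the difference itself, in 169 genes (139 of them called in the former comparison alone, 8 in the latter alone, 21 in both and 1 in neither; 13 are receptor or immunoglobulin segments). The costimulatory receptor gene Tnfrsf9 had a difference of 5.61 on the log2 scale (adjusted p = 0.000131), and the chemokine genes Ccl4 and Ccl3 had 4.71 and 5.10. For the exhaustion-linked genes, differences were 2.56 for Tox (adjusted p = 0.0269), 2.95 for Pdcd1, 3.99 for Lag3, 5.73 for Egr2 and 6.90 for Nr4a2, and for Calcb 5.63. In the other direction stood Gzmb at -2.53 and Cxcr6 at -3.39, higher in marker-high cells, and Klrg1 at -7.27, S1pr5 at -9.68, Ifit3 at -4.37, Tnfrsf25 at -8.29, Kcnj8 at -11.77 and Trim30c at -12.88, abundant in OT-I cells. For genes near 0 in a group, these differences depend on the prior count. Leaving out 1 library moved the 169 to between 71 and 305 (100 without marker-low 1, 105, 106 and 96 without OT-I 1, 2 and 3, and 109, 71 and 305 without marker-high 1, 2 and 3), and DESeq2 gave 793.

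Of 100 drawn regroupings of the 12 libraries (200 are possible), 10 gave at least 169 genes, the real one included, and the highest other gave 1578. The 9 others as large were among 10 that kept SV40-I apart from OT-I libraries, and the highest without that split gave 10, so the size of the SV40-I against OT-I effect fixed this tally and it says nothing about chance. For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes: 1479 against a highest other of 17 for SV40-I and OT-I, 196 against 0 for marker-high and marker-low, 874 against 3 for SV40-I at days 20 to 21 and marker-high, and against naive cells 2954 and 1 (SV40-I), 1206 and 1 (OT-I), 3841 and 0 (marker-high) and 2754 and 0 (marker-low).

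Macrophage transcripts were unevenly spread over the day 8 to 9 libraries, at 742 to 8854 summed CPM in marker-low and 4091 to 6058 in marker-high libraries. With the summed macrophage list as a covariate, 138 of the 196 genes called between marker-high and marker-low cells stayed called among 156, while the tissue residency list lost its call (adjusted p = 0.116). The macrophage list itself kept a median of 0.80 with that covariate, after 0.98 without it, so most of its difference was not taken out. The test therefore cannot decide whether macrophage RNA lies behind the gene calls or the residency list, and both stay open. The difference in sorting gate and the genotype letters in the column headings stay open as biological explanations and were not tested.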

How the results depend on the processing

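The removal of 3 day 20 to 21 libraries, the removal of 2 day 8 to 9 libraries, the macrophage covariate and the fit without robust estimation were chosen only after the result was seen.

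Of 176 counts of calls under alternatives other than leaving out a library, 139 stayed within 1.5 times; of 1704 values of named genes 1551 kept their direction and side of the threshold, 113 lost and 36 gained a call; of 797 list values 726 kept theirs, 53 lost and 17 gained a call. Except where fewer libraries were fitted, the cause was not tested. DESeq2 called 1387 higher and 1127 lower for SV40-I against OT-I, 341 and 412 for marker-high against marker-low, 393 and 101 for TOX-GFP, 992 and 1275 for SV40-I against marker-high, and against naive cells 1756 lower (SV40-I), 1650 and 802 (OT-I), 2311 lower (marker-high) and 2641 and 1847 (marker-low); differences of effects were 793 and 160 genes. With limma-voom, marker-high against marker-low gave 150 and 193, SV40-I against marker-high 501 higher, and the TOX-GFP minus marker-high difference 36; RLE size factors gave 3 there, 100% of them higher against 80% of 5. Without a filter TOX-GFP gave 6 higher and SV40-I against marker-high 171 higher, and with the stricter filter the latter gave 457 higher and marker-high against marker-low 122 higher. Fitting the compared groups alone gave 1 and 3 for marker-high against marker-low and 61 and 264 for SV40-I against marker-high. The number in the table names as a block gave 392 and 415 for SV40-I against OT-I and 2 and 3 for marker-high against marker-low. Only libraries that share a number across the compared groups carry the effect there, so fewer libraries stand behind these counts. Removing 3 day 20 to 21 libraries left 83 and 144, and removing 2 day 8 to 9 libraries left 45 and 62.

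Leaving out 1 library gave 423 to 597 higher and 449 to 514 lower for SV40-I against OT-I, 13 to 73 and 25 to 86 for marker-high against marker-low, 0 to 1021 and 0 to 379 for TOX-GFP, 50 to 772 and 261 to 897 for SV40-I against marker-high, and against naive cells 1269 to 1505 and 792 to 911 (SV40-I), 549 to 659 and 189 to 234 (OT-I), 1542 to 2150 and 745 to 1431 (marker-high) and 988 to 1522 and 414 to 913 (marker-low). The differences of effects ranged from 71 to 305 and 0 to 10. Depth limits a gene without counts in a library to at most 0.0554 to 0.0811 CPM.

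The correlation of SV40-I against OT-I with marker-high against marker-low effects was 0.176 without a filter, 0.557 with the stricter filter and 0.594 above 3 in mean log2 CPM (0.257 to 0.33 leaving out a library); that of marker-high with TOX-GFP effects was 0.031, 0.276 and 0.323 (0.071 to 0.163). The correlation of SV40-I against OT-I with TOX-GFP effects ranged from -0.037 to 0.057, below 0 without OT-I 1 (-0.003), SV40-I 2 (-0.037), SV40-I 3 (-0.011) and GFP 2 (-0.002). The set lower with TOX-GFP, at -0.718 in marker-high cells, lost its call with an estimated correlation. Signs reversed for Lag3 with TOX-GFP (0.076 with limma-voom, 0.039 with 19 libraries, 0.208 and 0.662 without TOX-GFP 1 and GFP 1, with a range from -0.491), Oas1a in marker-high cells (-0.044 with the table-name block, -0.136 without marker-high 3, in a range up to 0.984), Tox in marker-low against naive cells (0.195 without marker-low 3, 0.048 without naive 3, in a range from -0.451), the interferon list in marker-high cells (-0.452 without marker-high 3, in a range up to 0.686) and the B cell list with TOX-GFP (-0.376 with the stricter filter).

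Label numbers were not used as pairs, and the data did not settle whether they pair samples. Deviations of same-numbered libraries correlated at 0.34, 0.007 and 0.343 for SV40-I and OT-I and at 0.195, -0.405 and -0.119 for marker-high and marker-low. Libraries that share a number in the table names correlated at 0.068 and 0.328 for SV40-I and OT-I, where the other pairs ranged from -0.423 to 0.343. For marker-high and marker-low such libraries correlated at -0.02 and 0.331, where the other pairs ranged from -0.405 to 0.284. In culture same numbers gave 0.201 and different numbers -0.201, where 2 libraries per group leave only the sign informative. Trbv29 was lower in library 1 of both cultured groups (698 with TOX-GFP and 1040 CPM with GFP) than in library 2 (1290 and 2140 CPM). Pairing in culture therefore stays open. With the replicate number as a block, 721 genes were higher and 709 lower for SV40-I against OT-I, 59 and 85 for marker-high against marker-low (residency and transcription factor lists not passing, at 0.0643 each), 312 and 543 for SV40-I against marker-high, and 0 for TOX-GFP, where Lag3 stood at 0.067 and the sort marker list passed (median 0.878, adjusted p = 0.0201). Not every library correlated best with its own number.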

Other observations

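The tests of RNA of other cells, of dilution and of cell cycle sums and positions of the later cells were chosen only after the result was seen; the tests of the position of library 3 and of shared cell cycle genes were chosen before, but the rule of the latter was tightened afterwards to ask that the bound be passed by more than the spread on leaving out a library, which turned its outcome from excluded to undecided.

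Of the ex vivo groups, the marker-low cells of days 8 to 9 had the highest means of the cytokine genes Ifng, Xcl1 and Tnf. Ifng stood at 395 ± 123 CPM there, against 86.9 ± 61.1 in marker-high, 46.4 ± 15.8 in OT-I and 27.2 ± 4.51 in SV40-I cells at days 20 to 21 (n = 3 each). The chemokine gene Xcl1 stood at 580 ± 169 CPM in marker-low and 173 ± 159 in marker-high cells. For Tnf the levels were 184 ± 15.4 CPM in marker-low and 27.4 in marker-high cells. Between marker-high and marker-low cells Tnf passed the edgeR test (adjusted p = 0.0172), while Ifng and Xcl1 had an adjusted p = 0.0843 and 0.558. Ccl4 reached 1326 CPM in marker-low cells, beside 1250 in SV40-I cells at days 20 to 21, 610 in marker-high and 104 in OT-I cells. Tnfrsf9 stood at 1111 CPM in marker-low, 1545 in marker-high and 1564 in SV40-I cells at days 20 to 21, against 23.1 in OT-I and 19.2 in naive cells.

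Calcb separated groups of the same receptor, at 208 ± 53.6 CPM in SV40-I cells at days 20 to 21, 97.1 ± 24.0 in marker-high and 0.963 ± 0.246 in marker-low cells, with no counts in naive cells. Itgae, which encodes the integrin CD103, stood at 510 ± 130 CPM in naive cells and at no more than 7.67 CPM on average in any lesion group. Klrg1 and Cx3cr1 were at 290 and 282 CPM in OT-I cells, while the means of Klrg1 in SV40-I lesion groups were 1.07 to 6.97 CPM and those of Cx3cr1 10.9 to 32.9 CPM. The TOX-GFP and marker-high effects differed in 5 genes by a test of the difference in 1 fit of 19 libraries: Aqp3 (3.63), Nfkbid (3.60), RP23-284K1.6 (12.22), H2-Q2 (5.53) and Cd8a (-1.61). Leaving out TOX-GFP 1 left 2 of that kind, marker-low 2 or 3, marker-high 2 or TOX-GFP 2 left 3, GFP 1 or 2 left 0, and leaving out marker-low 1 or marker-high 1 gave 9 and 10. Xist stood at 64.9 to 109 CPM in the cultured libraries, and the Y-linked Ddx3y at 0.126 to 10.5 CPM in the ex vivo libraries.

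Marker-high library 3 stood apart from libraries 1 and 2, with Tcf7 at 1.57 CPM against 94.3 and 71.0 and summed cell cycle transcripts of 5411 against 9239 and 10140 CPM. A library of SV40-I cells from days 20 to 21 under the wrong label is argued against, since cell cycle sums there were 1029 to 1653 CPM and Gzmb stood at 935 to 1593 against 3808 CPM, although Tcf7, at 1.01 to 2.44 CPM, was as low. The median position of 1669 genes was 0.58 (quartiles 0.34 and 0.83) on a scale from libraries 1 and 2 (0) to the later cells (1), where later libraries held out in turn lay at 0.90, 0.87 and 0.99. By the rule set beforehand this median alone left the wrong label undecided. The argument against it rests on the cell cycle sums, Gzmb and held-out positions, which were looked at after the result was seen. Erythroid and platelet transcripts were 11 times those of libraries 1 and 2 (1397 CPM), so that RNA is present, but other cells diluting the T cell transcripts is argued against, since T cell identity genes stood at 1.05 times while naive and memory genes stood at 0.201 times. An advanced state of the cells may also account for the difference and was not tested.

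The 50 genes with the smallest p-values among those higher with TOX-GFP in culture were, as a set, also higher in marker-high than marker-low cells, and a candidate explanation is that both comparisons share cell cycle genes, of which 5 were among the 50. With the summed cell cycle list as a covariate, the median of the 50 genes was 0.65 after 0.92 without it, above a bound of 0.61 by less than its spread on leaving out a library (SD 0.26, range 0.62 to 1.31), so the explanation stays undecided. In that fit the set had a camera p of 0.0139 (0.159 with an estimated correlation), and Tox was at 2.94 (adjusted p = 0.0159). A hypothesis that TOX itself raises these genes in marker-high cells was not tested.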
